A study of Mus musculus with 24 samples.

How the data were processed

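The authors deposited a table of whole-number counts for 55487 Ensembl gene IDs in 24 libraries. Per the submitters' processing notes, bcl2fastq 2.20.0, HISAT2 and StringTie were used with the build mm9; the notes give no roles, settings, strand or annotation version. Per the labels' protocols, tumors were digested with Liberase, red cells were lysed, cells were sorted as CD45+ CD11b+ F4/80+, and total RNA went into an Illumina Nextera XT ultra low input protocol with 6 replicates of each sample. Gene symbols, positions and lengths were taken from GENCODE M21 (GRCm38) by gene ID; 55141 IDs had a symbol and 55227 a length. Coordinates in the text are those of GRCm38 and not of the build in the notes.

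Everything else was computed from the deposited counts in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. For the genotype, the counts of the 6 libraries of a tumor were summed and 2 APC-KO sums were set against 2 APC-WT sums by edgeR's quasi-likelihood test, with filterByExpr (53705 genes), TMM and Benjamini-Hochberg adjustment at 0.05. For tumors within a genotype and for the 4 pairs of an APC-KO and an APC-WT tumor, the 24 libraries were fitted by the same test with a mean per tumor (45451 genes), so those p-values measure the spread between libraries. Adjusted p-values in the text are from edgeR unless another tool is named. SE of a log2 change is the change divided by the square root of its F statistic, and log2 CPM used a prior count of 2.

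A total of 42 gene lists were fixed beforehand: 26 macrophage programmes, 12 sets of cell markers and 4 technical sets. They were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation and with fry, and their members also with the p adjusted over the list alone. The tests, the lists, the rule for named genes and a set of alternatives were fixed before the data were examined.

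Chosen after the data had been seen were the following. Loci sharing at least 0.4 of their 15-mers with Gm10800 were called satellite-like (12 loci). Background per kb of exon was estimated from 1972 receptor genes (1407 Olfr and 565 Vmn). Expressed genes had a mean CPM of at least 10 over the 4 tumors and at least 10 times their expected background (3944 genes, 3941 with length and GC content, 3772 with a principal isoform). Scaled CPM uses the TMM-scaled total of these genes as the library size. The length offset is a loess fit (span 0.5) of each tumor's log2 level on the log2 length of the longest transcript, and further offsets used the principal isoform or length with GC content.

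Genes were named by this rule. In the genotype comparison these were the 10 genes each way with the largest change among those past the threshold, at 10 CPM or more in the higher genotype and without overlap of the tumors. Since 0 passed, the places went to genes past the threshold in all 4 pairs, ranked by their smallest change. For each of 10 lists described up to 4 members with the smallest p were named, and 17 genes always. Within a genotype these were the 5 genes each way with the largest change past the threshold, at 10 CPM or more in the higher tumor. Genes without a symbol and segments of immunoglobulin or T cell receptor genes were passed over, and 1 gene that the rule takes is not reported here. Further genes were named after their values were seen: up to 4 per list of those called with 1 sign under no offset and under each offset and in all 4 pairs, within a genotype up to 4 list members with the smallest p, and the macrophage markers with a positive change after the offset. Malat1 and the genes ranked before it were named from all expressed coding and lincRNA genes that meet the first of these conditions.

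On simulated counts with 200 changed genes, the test on sums of 2 against 2 tumors over all genes recovered 0% of changes of 1 log2 unit and 3% of 2 units with 0 false calls. Background was alike in those simulated tumors. With no change in expression but the measured background and satellite-like counts added, the same test called 10070 genes. The median expressed gene then lay at -3.51, and among expressed genes alone at 0.003 with 22 calls. Tumors varied less in this simulation than in the data. Among expressed genes with a simulated length trend the test recovered 65% and 95% with 1084 false calls (29.0%) without the offset, and 83% and 100% with 12 false calls (0.321%) with it. The test on libraries of 6 against 6 recovered 90% and 100% with 15 false calls (0.0332%). Of 41 simulated lists of 20 expressed genes 1 was moved by 1 log2 unit. With the length offset its adjusted p was 4.22e-65 in camera with the preset correlation, with 0 unmoved lists called, and 0.255 with an estimated correlation. Genes were drawn independently, so this does not show how often the preset correlation falsely calls lists of genes that vary together.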

Results

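Tumor-associated macrophages were sorted as CD45+ CD11b+ F4/80+ cells from orthotopic tumors of MC38, a mouse colon carcinoma line, grown in C57BL/6J mice. The tumor cells either carried Apc, the tumor suppressor that restrains Wnt signalling, or lacked it, here called APC-WT and APC-KO. RNA of 4 tumors, 2 per genotype, was sequenced by an ultra low input protocol, with 6 libraries per tumor and 24 libraries in all. Total counts per library ranged from 74972634 to 93568353 in APC-WT tumor 1 and from 28018638 to 46837543 in APC-WT tumor 2. They ranged from 8895722 to 19328572 in APC-KO tumor 1 and from 13464061 to 17196820 in APC-KO tumor 2. Summed over 6 libraries, the tumors had 488977630, 219243647, 76507424 and 91084172 counts in that order. The labels describe the 6 libraries as replicates of one sample, so their spread is technical or lies within a tumor, and the tumor was the unit of replication for the genotype.

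The composition of the libraries differed between genotypes. Loci that resemble the satellite repeat gene Gm10800 (chromosome 2, 98666547 to 98667301, GRCm38) took 37.9% ± 0.42 and 38.5% ± 0.756 of the counts of APC-KO tumors 1 and 2 (SD, n = 6 libraries each). They took 1.32% ± 0.0796 and 7.05% ± 0.280 in APC-WT tumors 1 and 2. Olfactory and vomeronasal receptor genes held 0.0345%, 0.232%, 0.807% and 0.823% of the counts of APC-WT tumors 1 and 2 and APC-KO tumors 1 and 2. At least 99.5% of these 1972 genes had a count in each tumor. Spread over all genes by exonic length, a background at that rate amounted to 0.751%, 5.05%, 17.6% and 17.9% of the counts. The 3944 genes called expressed here (3941 with an annotated length and GC content), with a mean of at least 10 CPM and at least 10 times their expected background, held 81.7%, 73.6%, 33.2% and 31.8% of the counts. Gene levels below are therefore given as scaled CPM, relative to the counts of expressed genes. Scaled CPM carry no length offset, while log2 changes of single genes between genotypes carry it unless stated otherwise, so the 2 can differ. Other near-silent coding genes had 1.35 and 1.36 times the counts per kb of the receptor genes in APC-KO tumors 1 and 2. That ratio was 1.00 in APC-WT tumor 2, so the expected background of a gene may be too low in APC-KO.

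**Figure D1:**
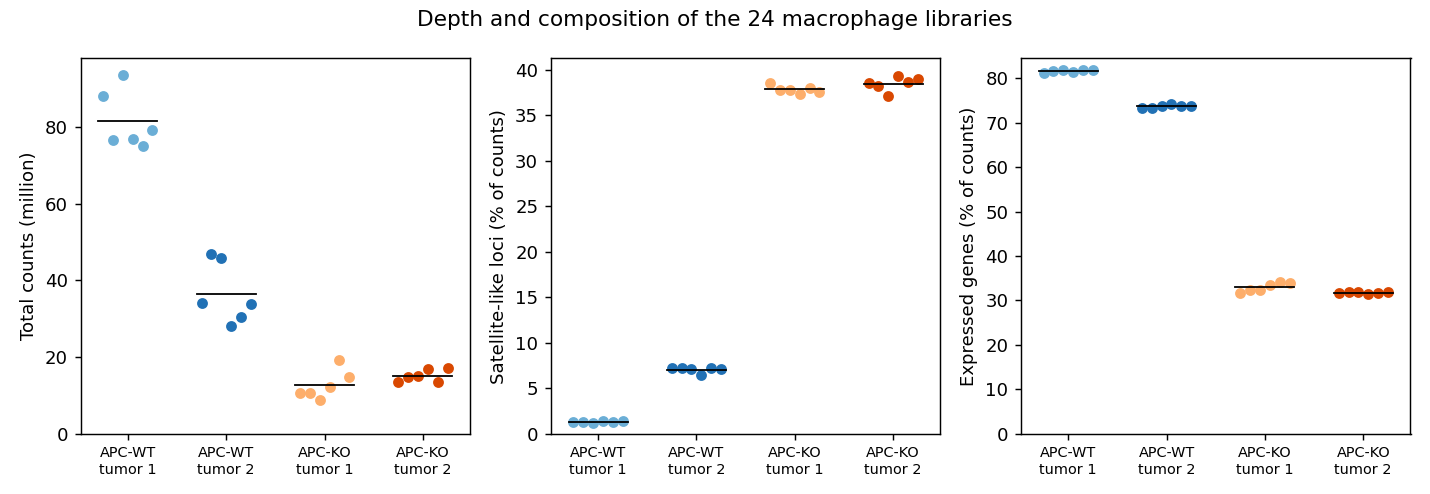
Total counts, the percent of counts in 12 satellite-like loci and the percent of counts in expressed genes, for each of the 24 libraries (points) with the mean of each tumor (lines). The satellite-like share lies between 37.2% and 39.4% in the 12 APC-KO libraries and between 1.18% and 7.24% in the 12 APC-WT libraries.

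Apc itself (ENSMUSG00000005871, chromosome 18, 34220924 to 34322552, GRCm38) read 44.5 ± 2.65 and 34.0 ± 2.26 scaled CPM in APC-WT tumors 1 and 2 and 105 ± 11.1 and 102 ± 6.14 in APC-KO tumors 1 and 2 (library mean ± SD, n = 6). Background of 1.23, 8.80, 63.2 and 63.8 scaled CPM was expected in these tumors. The macrophages come from the host, whose Apc was not targeted, so this gene does not check the labels. Transcripts of the enzyme named in the series title, Tdo2 (ENSMUSG00000028011, chromosome 3, 81957090 to 81976202, GRCm38), which opens the tryptophan ring on the way to kynurenine, stood at 0.345 ± 0.162, 3.05 ± 0.516, 15.4 ± 2.86 and 15.8 ± 2.23 in the 4 tumors in that order. Background of 0.297, 2.12, 15.2 and 15.4 scaled CPM was expected for Tdo2 in the same order, so Tdo2 lay near background in all 4 tumors.

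The first comparison asked how macrophages from APC-KO tumors differ from those of APC-WT tumors. Genes of the interferon gamma response, antigen presentation on MHC class II, and phagocytosis were lower in APC-KO once the change that follows transcript length had been removed. Ribosomal protein genes and mitochondrially encoded genes were then higher. With TMM over all genes the last 2 groups were lower, at medians of -2.24 and -0.82, but less so than the median expressed gene at -4.01. None of these 5 lists passed with an estimated correlation (adjusted p from 0.716 to 0.776), a test in which a simulated list of 20 genes moved by 1 log2 unit did not pass either (0.255). The preset correlation was not tried on simulated lists of genes that vary together. Without the offset MHC class II (median -0.68, adjusted p = 0.123) and phagocytosis (-0.53, 0.0718) did not pass. By fry with the offset the first 3 lists passed (0.0305 for each) and the last 2 did not (0.0511 and 0.0814). Whether background counts raised the last 2 lists was not tested. Itgam (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491, GRCm38), which encodes the CD11b antigen of the sort, fell from 1596 ± 30.6 and 1783 ± 86.7 scaled CPM in APC-WT to 274 ± 50.03 and 276 ± 27.6 in APC-KO (SD, n = 6 libraries). Its log2 change with the length offset, which these levels do not carry, was -2.05 ± 0.152 (SE, n = 2 tumors per genotype, adjusted p = 0.00271). Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, GRCm38), the invariant chain of MHC class II, fell from 21665 ± 186 and 26648 ± 422 to 12929 ± 342 and 10897 ± 196. With the length offset, which enlarges the fall, its log2 change was -1.61 ± 0.190 (adjusted p = 0.00466). Rpsa, a protein of the small ribosomal subunit, rose from 109 ± 9.07 and 95.1 ± 7.49 to 630.5 ± 63.7 and 780.2 ± 45.6 (log2 change with the length offset 2.67 ± 0.192, adjusted p = 0.00252). Of the 3941 expressed genes 993 rose and 971 fell with a transcript length offset, by edgeR's quasi-likelihood test on tumor sums with Benjamini-Hochberg adjustment. Without the offset 1288 rose and 1208 fell, and 745 of the higher and 771 of the lower calls were shared, with 56 called in opposite directions. With the offset and 1 tumor against 2, no gene passed when APC-KO tumor 1 was left out and 296 passed when APC-KO tumor 2 was left out, against 1859 and 1925 without APC-WT tumor 1 or 2. The set of expressed genes and the offset were chosen after the composition of the libraries had been seen. The limit for expressed genes was on CPM of all counts, so APC-WT levels weighed more in it than APC-KO levels. Genes high in APC-WT alone passed it more easily than genes high in APC-KO alone. How far this raised the counts of lower list members below was not tested.

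The test as designed before the data were examined, edgeR on all 53705 genes passing its count filter, called 0 genes, with 18647 at an unadjusted p below 0.05 and a lowest adjusted p of 0.0974. On the same sums limma-voom called 0 and DESeq2 called 11470, of which 84 were higher and 11386 lower. Without APC-WT tumor 1 or 2 the count was 25572 or 28018, and without APC-KO tumor 1 or 2 it was 45 or 34. On these sums 37 of the 42 gene lists fixed beforehand were lower by camera with the preset correlation, 0 higher, and 0 passed with an estimated correlation or by fry. Scaling over all genes (TMM) moved the median expressed gene by -4.01 log2 units between genotypes and the median of all tested genes by 0.27, so changes on that scale are relative to -4.01. Simulated background without a change in expression moved the median expressed gene by -3.51 on that scale. Scaled to the expressed genes, 30228 genes were higher and 1343 lower, the median expressed gene lay at 0.01 and the median of all genes at 3.57.

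The change between genotypes followed transcript length. Across the 3941 expressed genes the rank correlation of the log2 change with the length of the longest annotated transcript was -0.567. It lay between -0.523 and -0.566 in the 4 pairs of an APC-KO and an APC-WT tumor (genes are not independent replicates). The 43 genes of up to 500 bp had a median change of 2.22 and the 635 genes of the second longest bin, up to 6000 bp, one of -0.55. Between the 2 APC-WT tumors the correlation was -0.111 and between the 2 APC-KO tumors 0.0515. With the offset it was 0.00167.

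**Figure D2:**
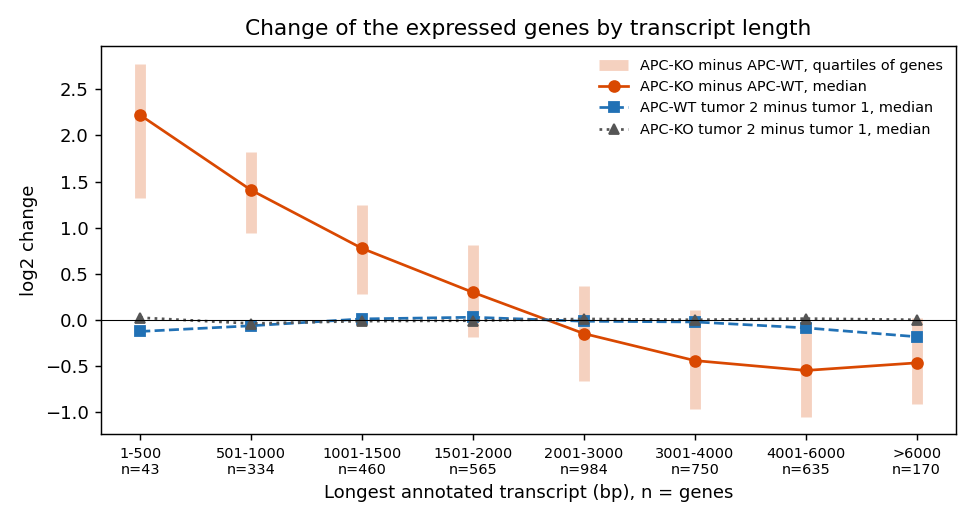
Median log2 change of the expressed genes (y axis) in 8 bins of longest annotated transcript length in bp (x axis, number of genes under each bin) for APC-KO minus APC-WT tumors, with quartiles of genes as bars, and for tumor 2 minus tumor 1 within each genotype. The genotype change runs from 2.22 at up to 500 bp to -0.55 in the second longest bin, while the medians within a genotype stay between -0.18 and 0.03.

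Among genes induced by interferon gamma, 18 of the 26 expressed members fell and 2 rose (19 and 2 when adjusted over the list alone). Their median was -1.11, adjusted p = 0.000808, and adjusted p = 0.716 with an estimated correlation and 0.0305 by fry. Cd274, which encodes the checkpoint ligand PD-L1, fell by 1.78 ± 0.368 on the log2 scale (adjusted p = 0.0174). The interferon-induced GTPases Irgm2, Gbp3, Tgtp1 and Gbp2b had changes of -1.54, -1.50, -1.33 and -1.86, each past the threshold (adjusted p from 0.00271 to 0.0251). Ido1, the other enzyme that opens the tryptophan ring, read 4.59, 9.04, 9.53 and 9.48 scaled CPM in APC-WT tumors 1 and 2 and APC-KO tumors 1 and 2, where background of 0.140, 0.997, 7.16 and 7.23 was expected. In the type I interferon response 16 of 33 members fell and 1 rose (18 and 1 when adjusted over the list alone). Its median was -0.64, adjusted p = 0.00117, and adjusted p = 0.776 with an estimated correlation and 0.155 by fry. Ifit2, which binds foreign RNA, had a change of -3.13 ± 0.346 (adjusted p = 0.00424) and Ifit3b one of -1.54 (0.0173). Ifi44 at -0.73 ± 0.298 did not pass, and Mx2 read 22.8, 20.2, 24.8 and 30.8 scaled CPM over an expected 0.277, 1.97, 14.2 and 14.3 in the same tumors. The counts of Ifit2 were uneven between replicates. It read 13.2 scaled CPM in library 4 of APC-WT tumor 2 and 472 to 506 in the other libraries of that tumor. Without APC-KO tumor 1 a test of 1 tumor against 2 called 0 genes, although the median of the interferon gamma list was -1.11 and -1.05 in the pairs with APC-KO tumor 2 and -0.68 and -1.02 in those with APC-KO tumor 1. Irgm2 read 38.3 and 36.3 scaled CPM in APC-KO tumors 1 and 2.

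On MHC class II presentation 8 of 10 expressed members fell and 0 rose (9 and 0 when adjusted over the list alone). Its median was -1.15, adjusted p = 0.00198, and adjusted p = 0.716 with an estimated correlation and 0.0305 by fry; without the offset it was -0.68 and the list did not pass (adjusted p = 0.123). H2-Ab1 and H2-Eb1, beta chains of the class II molecules, changed by -1.67 ± 0.218 and -1.13 ± 0.206 (adjusted p = 0.00560 and 0.0128). H2-DMb2, a chain of the peptide exchange factor, changed by -0.40 ± 0.111 (0.0398), against 0.16 without the offset. Ciita, the class II master regulator, H2-Oa and H2-Ob were below the limit for expressed genes. Ciita read 144, 175, 108 and 84.8 scaled CPM, H2-Oa 2.74, 4.805, 16.5 and 13.8 and H2-Ob 9.37, 17.7, 37.6 and 38.2. Background of 0.730, 5.21, 37.4 and 37.8 was expected for Ciita, 0.108, 0.768, 5.52 and 5.57 for H2-Oa and 0.412, 2.94, 21.1 and 21.3 for H2-Ob. Of 21 phagocytosis and complement genes 12 fell and 0 rose (13 and 0 when adjusted over the list alone). Their median was -0.74, adjusted p = 0.00123, and adjusted p = 0.716 with an estimated correlation and 0.0305 by fry, and without the offset it was -0.53 and the list did not pass (0.0718). Axl, a receptor for dying cells, fell by 1.94 ± 0.179 (adjusted p = 0.00331) and Itgb2, the beta chain that pairs with CD11b, by 1.47 ± 0.192 (0.00560). Mertk and its bridging ligand Gas6 did not pass, at -0.33 ± 0.374 and 0.69 ± 0.323 (adjusted p = 0.485 and 0.138). Cd36, a scavenger receptor, read 14.8, 43.1, 47.2 and 25.2 scaled CPM over an expected 0.275, 1.96, 14.1 and 14.2.

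Of 12 sort and pan-macrophage markers 8 fell and 0 rose (9 and 0 when adjusted over the list alone). Their median was -0.76, adjusted p = 0.00802, and adjusted p = 0.716 with an estimated correlation and 0.0305 by fry; without the offset it was -0.30 and the list did not pass (adjusted p = 0.197). Adgre1, which encodes F4/80, changed by -1.72 ± 0.150 (adjusted p = 0.00311), Csf1r, the receptor for the macrophage growth factor CSF1, by -1.76 ± 0.196 (0.00424) and Ptprc, which encodes CD45, by -0.99 ± 0.142 (0.00703). Among 14 checkpoint ligands and regulators 7 fell and 0 rose, also when adjusted over the list alone. Their median was -0.69, adjusted p = 0.0267, and adjusted p = 0.757 with an estimated correlation and 0.0385 by fry. Siglece, an inhibitory receptor for sialic acids, and Havcr2, which encodes TIM-3, changed by -1.83 and -1.56 (adjusted p = 0.00252 and 0.00277), while Adora2b at -0.69 did not pass (0.243). Pdcd1lg2 read 5.17, 9.07, 17.9 and 15.4 scaled CPM over an expected 0.150, 1.07, 7.69 and 7.77, and Tnfrsf14 5.34, 4.48, 8.34 and 7.61 over 0.110, 0.785, 5.64 and 5.70, in APC-WT tumors 1 and 2 and APC-KO tumors 1 and 2. Without APC-KO tumor 1 the offset test, 1 tumor against 2, called 0 genes, although the median of the 12 markers was -0.80 and -0.67 in the pairs with APC-KO tumor 2 and -0.98 and -0.70 in those with APC-KO tumor 1.

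Targets of the aryl hydrocarbon receptor, the transcription factor that kynurenine binds, had 5 of 7 expressed members lower and 0 higher, also when adjusted over the list alone. The list did not pass in camera but did in fry (median -0.91, adjusted p = 0.0555, and adjusted p = 0.716 with an estimated correlation and 0.0276 by fry). Over all its tested members scaled to the expressed genes its median was 0.30, with 6 higher and 5 lower. That lies between 0.01 for the median expressed gene and 3.57 for all tested genes on that scale. Tiparp, a feedback inhibitor of the receptor, fell by 0.91 ± 0.143 (adjusted p = 0.00861) and Nfe2l2, the regulator of antioxidant genes, by 1.22 ± 0.146 (0.00473). Without APC-KO tumor 1 the offset test, 1 tumor against 2, called 0 genes, although Tiparp read 149.7 and 149 scaled CPM in APC-KO tumors 1 and 2. Serpinb2 did not pass (-0.13 ± 0.291, adjusted p = 0.730). Ahr itself read 47.2, 71.7, 60.6 and 56.0 scaled CPM in APC-WT tumors 1 and 2 and APC-KO tumors 1 and 2, over an expected 0.472, 3.37, 24.2 and 24.4. In the same order Cyp1b1 read 0.915, 3.33, 41.7 and 38.0 over an expected 0.447, 3.19, 22.9 and 23.1. Aldh3a1 read 0.188, 0.529, 12.8 and 14.1 over 0.149, 1.06, 7.62 and 7.69 and Nqo1 7.29, 8.92, 11.2 and 13.5 over 0.119, 0.848, 6.09 and 6.15. In tryptophan and kynurenine metabolism 2 of 3 expressed genes fell and 0 rose, also when adjusted over the list alone. This list did not pass either (median -0.34, adjusted p = 0.203, and adjusted p = 0.776 with an estimated correlation and 0.132 by fry). Its median over all tested members scaled to the expressed genes was 2.36, with 11 higher and 3 lower. That also lies between the 0.01 of the median expressed gene and the 3.57 of all tested genes. Neither median by itself shows a fall or a rise. The 2 expressed genes that fell were Slc7a8, an amino acid transporter, at -1.13 ± 0.207 (0.0127) and Wars, the tryptophan tRNA ligase, at -0.34 ± 0.102 (0.0461). Kynu read 4.99, 5.54, 13.8 and 13.6 over an expected 0.470, 3.36, 24.1 and 24.4, above the expected background in APC-WT and below it in APC-KO. A level below background shows that the expected value of a single gene is approximate. Kmo read 6.42, 7.44, 13.2 and 14.5 over 0.361, 2.58, 18.5 and 18.7 and Slc36a4 37.1, 34.8, 27.7 and 26.6 over 0.5004, 3.57, 25.7 and 25.9.

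Ribosomal protein genes were higher in APC-KO relative to the other expressed genes but lower with TMM over all genes. With the offset 31 of 42 rose and 0 fell (33 and 0 when adjusted over the list alone). Their median was 0.90, adjusted p = 1.09e-09, and adjusted p = 0.757 with an estimated correlation and 0.0511 by fry. With TMM over all genes it was -2.24, against -4.01 for the median expressed gene. Rps20, Rpl18 and Rpl5 changed by 2.41, 2.00 and 1.83 (adjusted p from 0.00252 to 0.00292). Rpl15 and Rps2 changed by 0.84 and 0.38 (0.00964 and 0.0464), while Rps23 at 0.39 and Rpl4 at 0.17 did not pass (0.0757 and 0.435). With the length of the principal isoform in the offset Rpl15 stood at -0.18 and 27 members were called. Mitochondrially encoded genes had 11 of 13 members higher and 1 lower, also when adjusted over the list alone. Their median was 1.80, adjusted p = 0.00117, and adjusted p = 0.776 with an estimated correlation and 0.0814 by fry, and with TMM over all genes -0.82. The complex I chains mt-Nd5 and mt-Nd4 rose by 3.22 ± 0.283 and 2.49 ± 0.230 (adjusted p = 0.00319 and 0.00331). The respiratory chain genes mt-Cytb and mt-Co3 rose by 1.03 and 0.91 (0.0187 and 0.0150), and mt-Atp6 did not pass (0.27, 0.354). The gene mt-Atp8, whose 204 bp lie at the short end of the fitted trend, fell by 1.35 (0.0125) against a rise of 1.32 without the offset. Background was estimated from receptor genes, and whether its rate holds for these 2 lists was not tested. The APC-WT tumors 1 and 2 had an expected background of 0.751% and 5.05%. In APC-WT tumor 2, 13 of 13 mitochondrially encoded genes were higher than in APC-WT tumor 1, and 33 of 42 ribosomal protein genes lower. Without APC-KO tumor 1 the offset test, 1 tumor against 2, called 0 genes, although the median of the ribosomal list was 0.82 and 1.08 in the pairs with APC-KO tumor 2 and 0.71 and 0.96 in those with APC-KO tumor 1.

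**Figure D3:**
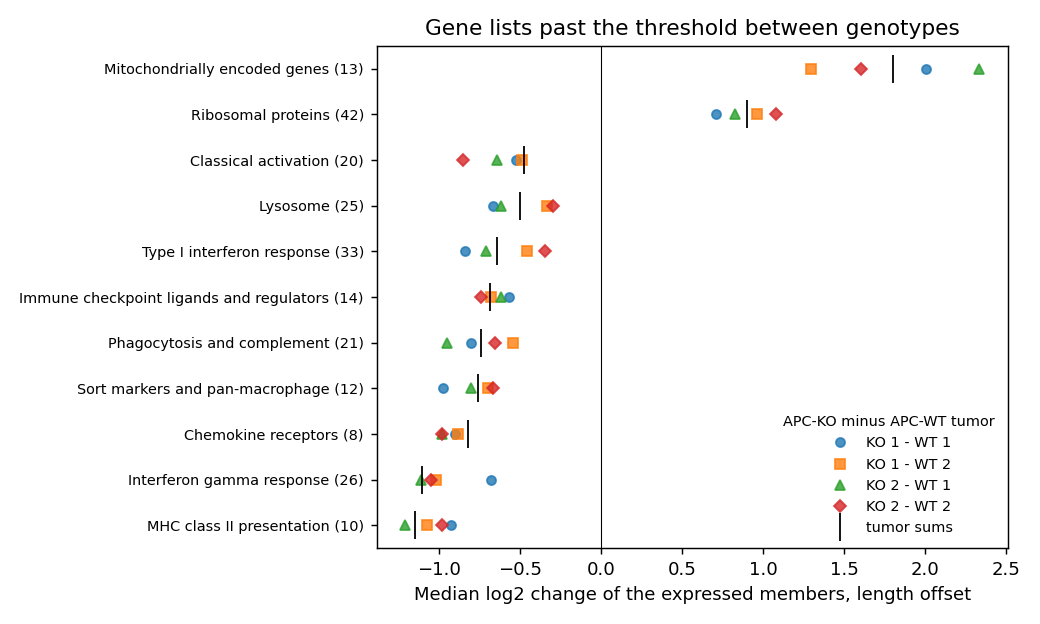
Median log2 change after the length offset (x axis) of the expressed members of the 11 fixed lists with an adjusted p below 0.05 in camera with the preset correlation, with the number of members in brackets; colored marks are the 4 pairs of an APC-KO and an APC-WT tumor and black bars the tumor sums. The interferon gamma list lies at -1.11 and the mitochondrially encoded list at 1.80 on the tumor sums, and 0 lists passed with an estimated correlation. With TMM over all genes the ribosomal and mitochondrially encoded lists were lower, at -2.24 and -0.82, but less so than the median expressed gene at -4.01.

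Other macrophage genes fixed for description did not pass with the offset. Arg1, the arginase of alternatively activated macrophages, read 1193, 1348, 2535 and 1136 scaled CPM (log2 change -0.04 ± 0.389, adjusted p = 0.943) and Nos2, the inducible nitric oxide synthase, 172, 1016, 373 and 75.6 (-0.93 ± 1.10, 0.505). Mrc1, the mannose receptor CD206, Spp1, which encodes osteopontin, and C1qa of the complement C1 complex had log2 changes of 0.23, 0.38 and -0.40 (adjusted p = 0.679, 0.275 and 0.238). Without the offset Spp1 rose by 0.91 ± 0.276 (0.0398). Cxcl5, a neutrophil-attracting chemokine, read 5.55, 3.07, 20.8 and 19.1 over an expected 0.142, 1.02, 7.31 and 7.38.

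Library counts, fitted with a mean for each tumor, separated 21655 of 45451 genes in the same direction in all 4 pairs of an APC-KO and an APC-WT tumor. Of these 10899 were higher and 10756 lower, and scaled to the expressed genes the split was 40826 higher and 1685 lower. Ranked by their smallest change among the 4 pairs, the 10 genes lower in APC-KO were Sept2, Raver1, Cpne1, Thbs1, Ifit2, Dmbt1, Itgam, Gbp2b, Fgl2 and Msn. Thbs1, which encodes the matrix protein thrombospondin, read 7647, 10045, 1255 and 554 scaled CPM (log2 change with the length offset -2.77 ± 0.474, adjusted p = 0.0108). Fgl2 read 1643, 1557, 252 and 267, Msn, the membrane linker moesin, 1584, 1663, 287 and 289, and Dmbt1 114, 349, 38.2 and 41.7. Sept2 read 53.1 and 16.6 in APC-WT, where 5 of the 6 libraries of APC-WT tumor 2 were at 0, and is listed at 0 in all 12 APC-KO libraries, although background alone would give 822 and 997 counts in APC-KO tumors 1 and 2. Raver1 (115, 85.5, 4.27 and 0.222) and Cpne1 (123, 136, 12.4 and 16.7) were also below an expected 13.6 and 17.7 in APC-KO tumor 1. The 10 that were higher, Aknad1, Gm3126, A730043L09Rik, Gm8661, Kcnn3, Gm8096, D830024N08Rik, Olfr462, Col13a1 and A630072M18Rik, read from 28.7 to 70.0 scaled CPM in APC-KO and at most 2.72 in APC-WT, over an expected 3.93 to 41.4 in APC-KO tumor 2. P-values of this count measure the spread between libraries of 4 tumors.

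The second comparison asked how far the 2 APC-WT tumors differ from each other. Relative to the other expressed genes, markers of epithelial cells, neutrophils, glycolysis and hypoxia were higher in APC-WT tumor 2, and type I interferon and resident macrophage genes were lower. Of 6 expressed epithelial markers 6 rose, with a median 2.04, adjusted p = 1.42e-08, and adjusted p = 0.00104 with an estimated correlation. Krt19, a keratin, rose from 31.0 ± 2.29 to 133 ± 3.90 and Epcam, an adhesion molecule, from 14.2 ± 1.62 to 56.6 ± 3.86 scaled CPM (SD, n = 6 libraries). Neutrophil genes had 10 of 11 higher and 1 lower (median 1.30, adjusted p = 4.61e-07, and adjusted p = 0.000849 with an estimated correlation), among them S100a9, a subunit of calprotectin, at 2.16 ± 0.0580 (adjusted p = 2.24e-19). Glycolysis genes had 16 of 18 higher and 1 lower (median 0.54, adjusted p = 2.21e-09, and adjusted p = 0.00400 with an estimated correlation). Hypoxia genes had 9 of 15 higher and 1 lower (median 0.38, adjusted p = 0.000356, and adjusted p = 0.00327 with an estimated correlation), with Ero1l at 1.59 ± 0.0551 and Ndrg1 at 1.60 ± 0.0571 (1.93e-17 and 3.66e-17). Type I interferon genes had 1 of 33 higher and 27 lower (28 when adjusted over the list alone; median -0.37, adjusted p = 3.28e-09, and adjusted p = 0.00306 with an estimated correlation), with Isg15, a ubiquitin-like modifier, at -0.58 ± 0.0302. Resident macrophage genes had 0 of 12 higher and 11 lower (median -0.54, adjusted p = 1.36e-08, and adjusted p = 0.000114 with an estimated correlation), with C1qa at -0.51 ± 0.0141. Mitochondrially encoded genes had 13 of 13 higher (median 0.50, adjusted p = 2.21e-09, and adjusted p = 0.0274 with an estimated correlation). Ribosomal protein genes had 33 of 42 lower and 0 higher (35 lower when adjusted over the list alone; median -0.19, adjusted p = 8.84e-08, and adjusted p = 0.0397 with an estimated correlation). Fibroblast markers had 4 of 4 lower (median -0.70, adjusted p = 0.00352, and adjusted p = 0.0148 with an estimated correlation) and peritoneal and serosal macrophage markers 3 of 4 higher and 1 lower (median 1.40, adjusted p = 0.0152, and adjusted p = 0.0347 with an estimated correlation). The other lists of this paragraph had the same counts when adjusted over the list alone.

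Among genes past the threshold with at least 10 CPM in the higher tumor, the 10 with the largest changes were, on the higher side, Ces2a, Cyp2c55, Jchain, Car1 and Vmn2r76, and, on the lower side, Max, Fcrls, Nr4a3, Gm45717 and Il10. Cyp2c55, an intestinal cytochrome P450, read 15.4 and 254 scaled CPM in APC-WT tumors 1 and 2, Car1, the colonic carbonic anhydrase, 72.4 and 654, Ces2a 1.18 and 19.5, and Jchain, which joins antibody chains, 2.42 and 24.6. The vomeronasal receptor gene Vmn2r76 read 2.30 and 17.9, where background of 2.03 and 14.5 was expected. Max, the partner of Myc, read 100.1 and 24.9, Fcrls 329.6 and 96.2, Nr4a3 97.4 and 30.6 and the anti-inflammatory cytokine gene Il10 89.0 and 28.8. Gm45717 read 118 scaled CPM in library 5 of APC-WT tumor 1 and 17.2 to 20.7 in its other 5 libraries, against 11.6 in APC-WT tumor 2. In all 33452 of 45451 genes passed in edgeR's test on library counts. The split was 21056 higher and 12396 lower with TMM over all genes, 12206 higher and 14265 lower with DESeq2's size factors, and 36526 higher and 1731 lower scaled to the expressed genes. Among the 3941 expressed genes 974 rose and 907 fell. With TMM the median expressed gene lay at -1.31, and the expected background share was 0.751% and 5.05% in these tumors.

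The third comparison asked the same of the 2 APC-KO tumors, whose background shares were alike. Hypoxia, glycolysis, neutrophil and chemokine genes were lower in APC-KO tumor 2, and cell cycle, resident macrophage and fibroblast genes were higher. Hypoxia genes had 13 of 15 lower and 0 higher (median -0.83, adjusted p = 3.78e-12, and adjusted p = 5.45e-06 with an estimated correlation). Ero1l, an oxidase of protein folding, fell from 414 ± 44.2 to 137 ± 10.1 scaled CPM and Slc2a1, the glucose transporter GLUT1, from 430.5 ± 28.7 to 162 ± 27.8 (SD, n = 6 libraries). Glycolysis genes had 17 of 18 lower and 0 higher (median -0.40, adjusted p = 9.37e-15, and adjusted p = 0.000631 with an estimated correlation). Neutrophil genes had 10 of 11 lower and 0 higher (median -0.70, adjusted p = 8.23e-09, and adjusted p = 0.000156 with an estimated correlation), with Lcn2, an iron-binding protein, at -1.56 ± 0.0941 (adjusted p = 1.42e-12). Chemokines had 14 of 18 lower and 3 higher (median -0.37, adjusted p = 6.32e-09, and adjusted p = 0.00347 with an estimated correlation), with Cxcl1 at -0.83 ± 0.0287 (2.64e-17). Cell cycle genes had 13 of 15 higher and 0 lower (median 0.39, adjusted p = 1.04e-06, and adjusted p = 0.000822 with an estimated correlation), with Stmn1, a regulator of microtubules, at 0.73 ± 0.0564. Resident macrophage genes had 9 of 12 higher and 2 lower (median 0.31, adjusted p = 0.000622, and adjusted p = 0.00327 with an estimated correlation). Fibroblast genes had 4 of 4 higher (median 0.79, adjusted p = 0.000213, and adjusted p = 0.00314 with an estimated correlation), with Dcn, the matrix proteoglycan decorin, at 0.93 ± 0.0599 (4.83e-12). Peritoneal and serosal macrophage markers had 3 of 4 lower and 0 higher (median -0.77, adjusted p = 0.000185, and adjusted p = 0.00314 with an estimated correlation). Mitochondrially encoded genes had 11 of 13 higher and 0 lower (median 0.30, adjusted p = 2.96e-07, and adjusted p = 0.0596 with an estimated correlation). Epithelial markers had 4 of 6 higher and 0 lower (median 0.32, adjusted p = 0.0223, and adjusted p = 0.104 with an estimated correlation). These counts were the same when adjusted over the list alone.

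Under the same CPM limit the largest changes between the APC-KO tumors were those of Nkg7, Il2rb, Egr1, Myl4 and Fcrls on the higher side and Ccl5, Nos2, Saa3, Ppbp and C3 on the lower side. Nkg7, a granule protein of cytotoxic lymphocytes, rose from 7.91 ± 5.20 to 59.0 ± 4.73 scaled CPM, and Il2rb, the interleukin 2 receptor beta chain, from 16.8 ± 4.97 to 53.7 ± 5.63. Egr1, an immediate early transcription factor, rose from 451 ± 59.1 to 1364 ± 65.8, Fcrls from 125 ± 10.1 to 375 ± 25.5, and Myl4 from 13.7 ± 2.30 to 40.9 ± 21.7 over an expected 18.2 and 18.4. Ccl5, a chemokine for T cells, fell from 602 ± 27.1 to 75.3 ± 6.25, Nos2 from 369 ± 21.3 to 74.9 ± 4.68, and the acute phase gene Saa3 from 1063 ± 38.1 to 242 ± 11.02. The complement gene C3 fell from 509 ± 18.1 to 128 ± 17.8 and the platelet chemokine gene Ppbp from 45.3 ± 7.26 to 10.5 ± 3.01. Over all tested genes scaled to the expressed genes, 9 of 22 T cell markers were higher and 0 lower (median 0.55). Of 16 NK cell markers 4 were higher and 1 lower (median 0.19). In all 1025 of 45451 genes passed, 457 higher and 568 lower, and 672 rose and 706 fell among the 3941 expressed genes. P-values within a genotype measure the spread between libraries within tumors, pooled over the 4 tumors, and say nothing about tumors in general. They treat the libraries of a tumor as alike, which they were not. A chi-square comparison of the counts of 2 libraries of APC-WT tumor 1 gave 6.94 per degree of freedom for libraries 2 and 4. For libraries 1 and 3 of that tumor it gave 126.

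**Figure D4:**
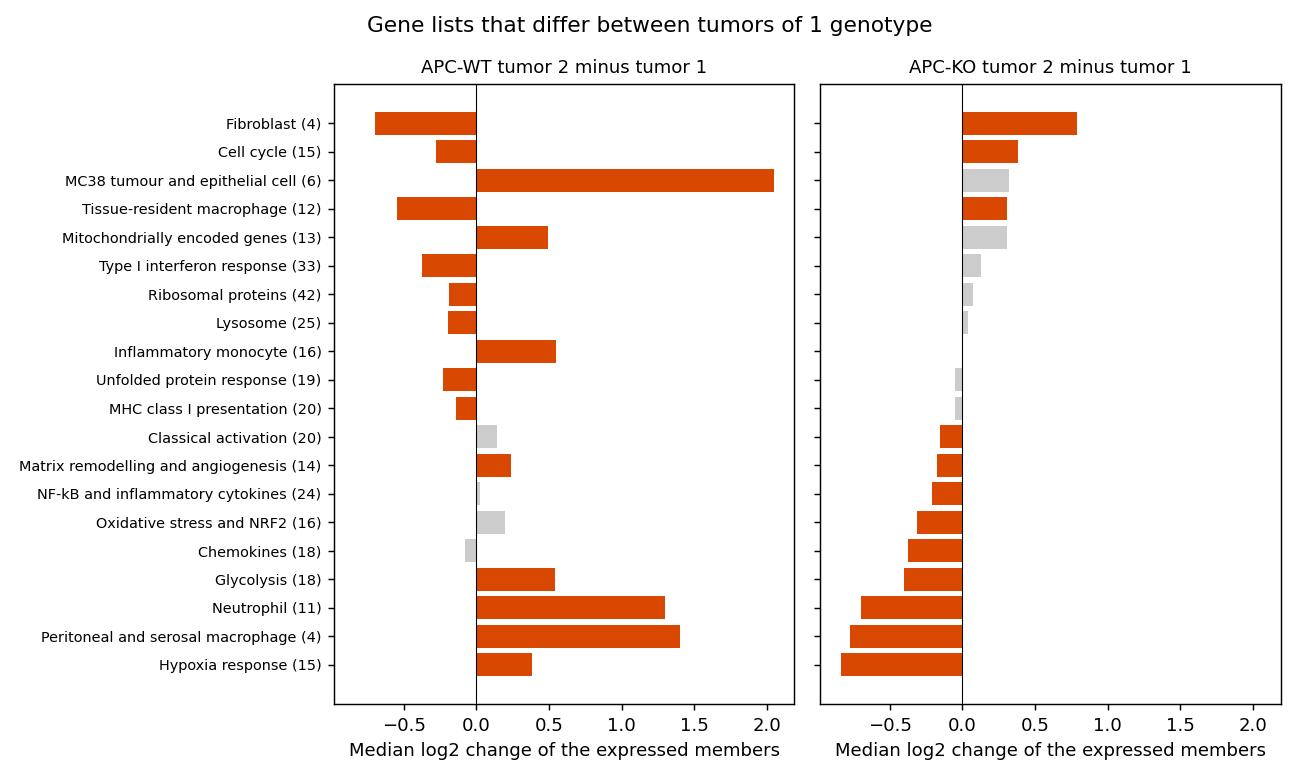
Median log2 change of the expressed members of 20 fixed lists (x axis) for tumor 2 minus tumor 1 in APC-WT (left) and in APC-KO (right), with the number of members in brackets. Dark bars have an adjusted p below 0.05 in camera with the preset and with the estimated correlation, grey bars do not; the hypoxia list lies at 0.38 in APC-WT and at -0.83 in APC-KO.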

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

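The test of genomic DNA was set before its result was seen, and the tests of receptor transcription and of depth after. The share of satellite-like loci and of olfactory and vomeronasal genes was larger in the APC-KO libraries. In APC-WT tumor 2 the satellite-like share of library 4 was 6.505% against 7.074% to 7.244% in the others, a gap to the nearest library of 0.7691 of the range. Genomic DNA in the libraries may be the source, since near-silent coding genes had counts on every autosome in the APC-KO tumors. The autosome farthest from the overall median per kb, chromosome 11 in APC-KO tumor 1, lay at 1.419 times it. Its 95% bootstrap interval, 1.209 to 1.685, reached past the limit of 1.5 set beforehand, so an even spread over autosomes was not shown. The ratio of other near-silent genes to the receptor families, 1.00 in APC-WT tumor 2, was not even in APC-KO either. Transcription of the receptor families is argued against, since other near-silent genes had at least 1.35 times the counts per kb of the families in both APC-KO tumors, and low depth is argued against, since the share varied by no more than 1.033-fold over libraries of APC-KO tumor 1 whose totals differed 2.173-fold. A difference in preparation between genotypes stays open, and no biological explanation other than transcription of these families was tested.

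Of 488 groups of 6 libraries, for 117 genes and the library measures, 46 had 1 library whose gap to the nearest other, as a share of the range, was beyond the 95% limit of Dixon's test. Chance flags about 1 in 20 groups, or 24.4 of these. Library 3 of APC-WT tumor 1 stood apart for 10 genes. Below, each gene is given with its scaled CPM and, in brackets, that gap as a share of the range. In APC-WT tumor 1 these were as follows. A730043L09Rik read 1.23 in library 5 against 0.436 to 0.716 in the others (0.646). A630072M18Rik read 1.97 in library 2 against 1.12 to 1.36 in the others (0.720). Raver1 read 81.0 in library 3 against 110.5 to 128 in the others (0.627). Tgtp1 read 212 in library 3 against 194 to 199 in the others (0.738). Ifi44 read 166 in library 3 against 153 to 155 in the others (0.823). H2-DMb2 read 65.7 in library 3 against 56.5 to 58.6 in the others (0.772). Aldh3a1 read 0 in library 4 against 0.175 to 0.244 in the others (0.719). mt-Atp6 read 149 in library 3 against 127 to 135 in the others (0.652). mt-Cytb read 155 in library 3 against 134 to 139 in the others (0.755). Gm45717 read 118 in library 5 against 17.2 to 20.7 in the others (0.965). Nkg7 read 3.10 in library 4 against 3.99 to 4.25 in the others (0.770). Egr1 read 3418 in library 3 against 3552 to 3587 in the others (0.792). Aif1 read 346 in library 3 against 309 to 320.2 in the others (0.695). H2-Ab1 read 7666 in library 3 against 7995 to 8112 in the others (0.738). Malat1 read 1679 in library 1 against 1535 to 1582 in the others (0.673). Rps20 read 70.5 in library 5 against 60.8 to 64.3 in the others (0.641). mt-Nd4 read 55.8 in library 3 against 47.8 to 50.5 in the others (0.669).

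In APC-WT tumor 2 the genes were as follows. Sept2 read 84.0 in library 3 against 0 in the others (1.0). Cpne1 read 97.8 in library 2 against 146 to 156 in the others (0.840). Ifit2 read 13.2 in library 4 against 472 to 506 in the others (0.929). Mx2 read 24.2 in library 6 against 19.6 to 21.2 in the others (0.652). Gm45717 read 1.82 in library 1 against 11.9 to 16.8 in the others (0.676). Nkg7 read 9.49 in library 5 against 6.68 to 7.66 in the others (0.653). Fcgr1 read 398 in library 1 against 413 to 421 in the others (0.645). Ndrg1 read 236 in library 1 against 250.4 to 257 in the others (0.699). Rpsa read 80.3 in library 1 against 94.9 to 99.98 in the others (0.741).

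In APC-KO tumor 1 the genes were as follows. Kcnn3 read 20.1 in library 2 against 45.5 to 57.8 in the others (0.673). A630072M18Rik read 48.2 in library 4 against 70.4 to 74.3 in the others (0.851). Raver1 read 36.2 in library 3 against 0 in the others (1.0). Irgm2 read 27.9 in library 5 against 39.1 to 42.9 in the others (0.744). Mertk read 89.3 in library 1 against 60.4 to 71.1 in the others (0.632). Ahr read 43.3 in library 3 against 59.1 to 63.3 in the others (0.787). Tiparp read 96.9 in library 1 against 149.7 to 168 in the others (0.745). Egr1 read 338 in library 1 against 444 to 500.5 in the others (0.655). Ero1l read 331 in library 1 against 408 to 453 in the others (0.631).

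In APC-KO tumor 2 the genes were as follows. Aknad1 read 13.8 in library 2 against 42.4 to 57.1 in the others (0.659). Olfr462 read 55.0 in library 5 against 57.0 to 58.0 in the others (0.664). Raver1 read 1.34 in library 2 against 0 in the others (1.0). Cpne1 read 47.5 in library 3 against 2.73 to 19.5 in the others (0.626). H2-Ob read 50.5 in library 2 against 32.7 to 38.7 in the others (0.662). Adgre1 read 327 in library 1 against 262 to 283 in the others (0.669). Rpl15 read 101 in library 6 against 71.9 to 80.3 in the others (0.708). H2-Ab1 read 4243 in library 2 against 4471 to 4599 in the others (0.642). Slc2a1 read 218 in library 3 against 143 to 156 in the others (0.826). Stmn1 read 304 in library 1 against 283 to 288 in the others (0.737).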

How the results depend on the processing

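The alternatives that use the expressed genes, a length offset, all genes scaled to the expressed genes, crossed blocks or no satellite-like loci were chosen after seeing the data; the others were planned. Where a result changed below, the cause was not tested, unless fewer genes or tumors entered the test. An exception is the shift of the expressed genes with TMM over all genes. Simulated background without a change in expression gave them a median of -3.51, against -4.01 in the data. When a tumor was left out, the lone tumor of its genotype was assumed to vary like the other genotype. The planned test without libraries far below the median total of their tumor was not run, since 0 libraries met its limit.

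The count of genes that differed between genotypes, 0 by edgeR with 18647 at an unadjusted p below 0.05, was 0 with DESeq2's size factors, without a count filter, with limma-voom, without satellite-like loci and at an absolute log2 change of at least 1. It was 7618 with upper quartile normalization, 11470 with DESeq2, 17653 on 24 libraries with the tumor as a random block, and 40472 on 24 libraries taken as independent. It was 12682 with libraries weighted equally, 31571 with all genes scaled to the expressed genes and 10913 at an adjusted p below 0.1. With the tumor number as a replicate block it was 966, and with the numbers crossed 1024. Without 1 tumor it ranged from 34 to 28018.

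Among the expressed genes the count of 2496 ranged from 1681 to 2516 without 1 tumor, was 1989 with the tumor number as a replicate block, and lay between 1844 and 2952 under the other settings of normalization, tool, background and offset. It was 1259 with the length offset and the tumor number as a block, and 2408 with the numbers crossed. With the length offset it was 1964, and from 0 (without APC-KO tumor 1) to 1925 without 1 tumor.

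The 33452 genes between the APC-WT tumors became 1881 among expressed genes, where fewer genes were tested, and ranged from 31428 to 32873 without 1 library number. The 1025 genes between the APC-KO tumors became 1568 with DESeq2 and 92 at an absolute log2 change of at least 1, and ranged from 794 to 940 without 1 library number. With the library number as a replicate block these counts were 32902 and 978. The 21655 genes in all 4 pairs became 42511 scaled to the expressed genes, 2748 among expressed genes and 12144 at an absolute log2 change of at least 1, and ranged from 19701 to 20075 without 1 library number. The 37 lists became 0 with an estimated correlation, 0 with fry, 8 among expressed genes, 11 with the length offset, 11 with length and GC content and 12 with the principal isoform; without 1 tumor the count ranged from 33 to 37.

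Of 66 named genes 65 kept their direction and side of the threshold with DESeq2's size factors, and 66 with limma-voom, without a filter and without either APC-KO tumor, in a test that calls few genes. Under other planned settings many came past the threshold in the same direction, 64 without APC-WT tumor 1, 64 without APC-WT tumor 2, 53 with DESeq2, 51 with upper quartile normalization, 61 with a random block, 53 with libraries weighted equally, 66 with libraries taken as independent and 9 with the tumor number as a replicate block (966 genes in all). Scaling all genes to the expressed genes moves them alike, the median expressed gene from -4.01 to 0.01, so a sign there says only which side of that shift a gene lies on. With it 26 changed sign, among them Ido1 0.48, Mx2 0.37, H2-Oa 2.00, H2-DMb2 0.16, H2-Ob 1.49, Cd36 0.32, Gas6 0.52, Nqo1 0.61, Kmo 1.00, Kynu 1.38, Rpl15 1.01, Rps2 1.36, Rpl4 0.67, Rps23 1.55, mt-Atp8 1.32, mt-Atp6 1.82, mt-Cytb 1.95, mt-Co3 2.29, Pdcd1lg2 1.23, Tnfrsf14 0.70, Arg1 0.53, Cxcl5 2.21, Spp1 0.91, C1qa 0.64 and Apc 1.43. Among expressed genes only, 13 changed sign: H2-DMb2 0.16, Gas6 0.52, Rpl15 1.01, Rps2 1.36, Rpl4 0.67, Rps23 1.55, mt-Atp8 1.32, mt-Atp6 1.82, mt-Cytb 1.95, mt-Co3 2.29, Arg1 0.53, Spp1 0.91 and C1qa 0.64. With the length offset 10 changed sign: Gas6 0.69, Rpl15 0.84, Rps2 0.38, Rpl4 0.17, Rps23 0.39, mt-Atp6 0.27, mt-Cytb 1.03, mt-Co3 0.91, Mrc1 0.23 and Spp1 0.38. With the principal isoform 10 changed sign: Gas6 0.82, Rps2 0.45, Rpl4 0.30, Rps23 0.49, mt-Atp6 0.36, mt-Cytb 1.16, mt-Co3 1.01, Arg1 0.10, Mrc1 0.29 and Spp1 0.46. Tdo2, at 0.08, was -0.16 with DESeq2's size factors, -0.16 with DESeq2, and from -0.39 to 0.38 without 1 tumor. The ribosomal list, at -2.24, was 1.84 among expressed genes, 0.90 with the length offset, 0.88 with length and GC content and 0.47 with the principal isoform. The mitochondrially encoded list, at -0.82, was 2.85, 1.80, 2.02 and 1.86 in that order, and from -1.85 to 0.0847 without 1 tumor.

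Background limits what can be seen for genes near it in both APC-KO tumors, where expressed genes held 33.2% and 31.8% of the counts. In both tumors these include Tdo2, Ido1, Kynu, Kmo and Cyp1b1. The depth of 8895722 to 19328572 counts in the libraries of APC-KO tumor 1 is a further limit there.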

Other observations

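Tests in this part were chosen after the results had been seen, except those of the 3 lists alone, of the principal isoform for the lists and of the library splits. Further gene lists were compared between genotypes among the expressed genes with the length offset. Lysosome genes had 10 of 25 lower and 1 higher (median -0.50, adjusted p = 0.00392, and adjusted p = 0.757 with an estimated correlation and 0.0814 by fry). Chemokine receptors had 5 of 8 lower and 0 higher (median -0.82, adjusted p = 0.0192, and adjusted p = 0.716 with an estimated correlation and 0.0330 by fry), with Cx3cr1, the fractalkine receptor, at -1.12 ± 0.286 (adjusted p = 0.0305). Without the offset 5 of 8 were lower and 0 higher, and the list did not pass (median -1.21, adjusted p = 0.0568). Classical activation genes had 8 of 20 lower and 1 higher (median -0.48, adjusted p = 0.0421, and adjusted p = 0.757 with an estimated correlation and 0.0814 by fry), with Ptgs2, the inducible cyclooxygenase, at -1.68 ± 0.320 (0.0142). It did not pass without the offset (median -0.39, adjusted p = 0.187) or with length and GC content (-0.39, 0.0639). Counts for these 3 lists were the same when adjusted over the list alone. Dissociation and immediate early genes did not pass (median -0.87, adjusted p = 0.0555, and adjusted p = 0.716 with an estimated correlation and 0.0566 by fry), but did without the offset (median -0.89, adjusted p = 0.0415) and with length and GC content (-0.88, 0.0487). Oxidative phosphorylation did not pass in camera but did in fry (median 0.15, adjusted p = 0.242, and adjusted p = 0.757 with an estimated correlation and 0.0305 by fry). Without the offset 21 of its 27 members were higher and 1 lower (median 0.96, adjusted p = 0.000201, and 0.877 with an estimated correlation). In camera with the offset cell cycle (0.25, 0.469), glycolysis (-0.12, 0.612) and hypoxia genes (-0.17, 0.826) did not pass. Alternative activation and Wnt targets passed in fry alone (median -0.39, adjusted p = 0.194, and adjusted p = 0.757 with an estimated correlation and 0.0385 by fry; median 0.53, adjusted p = 0.263, and adjusted p = 0.757 with an estimated correlation and 0.0276 by fry). With the offset none of the 6 tested lists of other cell types passed in camera, with medians of -0.60 for epithelial, -0.52 for neutrophil, -0.85 for fibroblast, -1.19 for B and plasma cell, 0.14 for dendritic cell and 0.13 for peritoneal and serosal macrophage markers. Without APC-KO tumor 1 the offset test, 1 tumor against 2, called 0 genes, although the median of the chemokine receptors was -0.98 and -0.98 in the pairs with APC-KO tumor 2 and -0.90 and -0.88 in those with APC-KO tumor 1.

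Among genes outside the lists, the nuclear RNA Malat1 read 1588, 2324, 12823 and 7202 scaled CPM in APC-WT tumors 1 and 2 and APC-KO tumors 1 and 2 (log2 change 2.86 ± 0.420, adjusted p = 0.00747; 0 genes were called without APC-KO tumor 1, in a test of 1 tumor against 2). Of genes with at least 20 expected background counts, 413 of 48490 were listed at 0 in APC-KO tumor 1 and 426 of 49070 in APC-KO tumor 2. In both tumors 327 were at 0, of which 87 were protein coding and 34, Sept2 among them, had a count in both APC-WT tumors.

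Short transcripts were higher and long transcripts lower in APC-KO, with a rank correlation of -0.567 across genes. Background counts are argued against, since the correlation was -0.6042 after subtracting them, and so are ribosomal, respiratory and mitochondrially encoded genes alone, since it was -0.5531 without them. A difference in RNA integrity or fragment length between preparations may underlie the trend. It cannot be told apart from the genotype, because each genotype has 2 tumors and the correlation between the APC-WT tumors was -0.1107. A biological change of short transcripts in APC-KO macrophages stays open and untested.

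The interferon gamma, MHC class II and phagocytosis lists were lower in APC-KO after the length offset with the preset correlation, and did not pass with an estimated one (adjusted p = 0.716 for each). A single tumor is argued against, since the highest median in the 4 pairs was -0.54. With the principal isoform the highest adjusted p of the 3 lists was 0.00159 in camera with the preset correlation. The lists had been picked for passing with a similar offset, so this test could hardly fail and no conclusion is drawn from it. The length trend as the whole cause is argued against for the interferon gamma list, whose median was -1.19 without an offset and -1.11 with it. Its highest adjusted p without an offset and with each length offset was 0.000888 in camera with the preset correlation (up to 0.877 over its alternatives, estimated correlations included). Removing the trend moved the MHC class II median from -0.68 to -1.15, since it raises these short genes (by 0.594 at their median), and the phagocytosis median, with members moved both ways, from -0.53 to -0.74, though both lists missed the threshold without an offset. More cells of other types in the APC-KO sorts cannot be told apart from a change in the macrophages, since 8 of 12 macrophage markers fell (median -0.76), with Itgam at -2.05 ± 0.152 but Fcgr1 at 0.39 ± 0.178 and Aif1 at 0.30 ± 0.142, a spread of 2.441 that 55.6% of random sets of 12 expressed genes reached, while none of 6 lists of other cell types was higher past the threshold (lowest adjusted p of those higher 0.612). A difference between preparations of the APC-KO and APC-WT tumors could still underlie the lists, as could a biological one, and the design cannot separate them.

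The 4 tumors allow 3 splits of 2 against 2, too few for a share under 0.05. Over all genes 3 of the 3 splits gave as many genes as the real split, with 0 for the real split and 18 for the highest other, which a real count of 0 fixes. Among expressed genes 1 of 3 did, with 2496 against 0, with the length offset 1 of 3, with 1964 against 0, and in all 4 pairs 1 of 3, with 21655 against 25. Of the planned 100 splits of 12 libraries 40 were run per genotype. The real split alone, 1 of 40, reached 33452 in APC-WT against 20516 for the highest other, and 1 of 40 reached 1025 in APC-KO against 175. Every other split mixes replicate libraries of 2 tumors, so the lead of the real split was close to fixed in advance. No conclusion about tumors is drawn from it.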
